A study of Mus musculus with 8 samples.

How the data were processed

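RNA was sequenced from 8 libraries, each made from the splenic AE9a-positive leukaemia cells of 1 moribund mouse. AE9a is a truncated form of the RUNX1-RUNX1T1 fusion protein that gives acute myeloid leukaemia in mice. Per the labels' protocols, cKit-positive marrow cells received a retrovirus that carried AE9a and a hairpin against Tet2 that is switched on by doxycycline, and the leukaemia was passed from primary to secondary recipients. Poly(A) RNA was enriched with oligo-dT beads and libraries were made with the NEXTflex RNA-seq kit, per the labels' protocols. The groups were 3 secondary recipients kept on doxycycline and given PBS (mice 16, 17 and 19), 2 taken off doxycycline and given PBS (mice 21 and 23, labelled Tet2-restored), 2 kept on doxycycline and given ascorbate (mice 28 and 30), and 1 primary recipient on doxycycline (mouse 12). Loss of doxycycline and restoration of Tet2 coincide in this design, so their effects are confounded.

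The authors deposited raw counts per gene symbol for 52459 genes, whole numbers without normalization, per the file headers and the values. A second table holds FPKM values that the authors deposited for the same libraries, rounded to hundredths. STAR, featureCounts and DESeq2 were used with the mm10 (GRCm38) genome, per the submitters' processing notes, which give no versions, settings or strand. The library factors recovered from the ratio of count to FPKM matched DESeq2 size factors (0.682 in both for mouse 28, on a relative scale) and not the column totals (0.754). As deposited, 26 symbols had been turned into calendar dates and 4 duplicated rows were given distinct names. Of the symbols, 91.7% were found in the GENCODE mouse annotation (release vM21), which was used for GC content, coordinates and overlaps. Transcript lengths were not taken from it but recovered from the ratio of count to the deposited FPKM. Of 171 genes named by rule, 170 were in the annotation and 60 share exonic bases with another gene. Without a stated strand setting, reads of such pairs and of antisense partners cannot be told apart.

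Depth ran from 18.1 M counts (mouse 28) to 34.2 M (mouse 12). Levels are given as CPM on TMM-scaled totals, with 95% Poisson intervals for the target genes. These intervals and the 3-count limit used for a count of 0 cover counting error only, since the libraries carry no molecular identifiers. The main test was the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3, robust fit) with TMM factors, its filterByExpr rule with a minimum count of 10, and Benjamini-Hochberg adjustment with a threshold of 0.05. Of 5 comparisons, 3 used 1 fit of the 7 secondary libraries in 3 groups: labelled restored against knockdown, ascorbate against PBS under knockdown, and labelled restored against ascorbate. Another set both arms together (4 libraries) against the 3 PBS knockdown libraries. The remaining one set the primary library against the 3 secondary PBS knockdown libraries in a fit of all 8, where the lone library is assumed to vary like the other groups. Standard errors (SE) are those of the log2 fold change, and levels are given as mean ± SD over libraries. The genes tested numbered 12137 in the first 3 comparisons, 11694 in the pooled one and 13024 in the last.

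The comparisons, their tests, 31 gene lists (DNA repair, cell cycle, blood lineages and other cell types of the spleen, interferon and inflammation, oxygen and redox, stress and metabolism), the naming rule and most alternatives were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 at its preset correlation of 0.01, and again with an estimated correlation and with fry, for lists of at least 5 tested members. Camera asks whether a list moved relative to other genes, and fry whether its members move one way on balance. Adjustment was over the lists of a comparison. Members were also adjusted over the list alone. The named genes are Tet1, Tet2, Tet3, Runx1 and Runx1t1, and in each comparison up to 12 genes per direction with the largest change among those past the threshold, with separate ranges in the groups and a mean of at least 5 CPM in the higher group. Predicted genes, clone-named loci and receptor segments were only counted, and the wording of this exclusion was widened to further clone names after values had been seen. Up to 4 members with the smallest p were named from each list with a member past the threshold. Where fewer than 10 genes passed, the 10 with the smallest p are given as values. Naming members that passed over the list alone was an extension chosen after values had been seen.

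Alternatives were DESeq2 size factors, library totals or upper quartile factors in edgeR; the Wald test of DESeq2 1.42.0; limma voom with quality weights; limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with at least 1 FPKM in 2 libraries; other filters on low counts; all 8 libraries or only the groups compared; a 2-fold minimum; and each library left out in turn. A length and GC trend fitted per library and given to edgeR as an offset, and a threshold of 0.1, were added after seeing the data. Shared controls were simulated 20 times with unchanged groups, and all 35 splits of the 7 secondary libraries into 4 and 3 were refitted. Random lists matched on expression, length and GC were drawn 10000 times.

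The scripts were tested on simulated data with the real libraries' means, depths and spread. Genes changed 2-fold were recovered in 46% of cases for the restored label, 40% for ascorbate, 36% for the arms compared, 41% for both arms together and 14% for the primary library. At 4-fold these shares were 78%, 75%, 69%, 82% and 69%. False calls among the remaining genes were 7, 9, 12, 4 and 12, and no changed gene was called with the wrong sign. A list lowered by 0.5 on the log2 scale was recovered by both forms of camera in each comparison, with 0 unchanged lists called. Each gene was drawn independently here, so the simulation does not show how often lists are falsely called when genes move together. In the real comparison for the restored label, the estimated correlation was 0.47 for the recombination list and 0.65 for the G1/S list. Splits of the 7 secondary libraries into 4 and 3 called 3 to 15 lists. With a simulated length trend, the offset cut false calls from 257 to 1 for the restored label, 271 to 0 for ascorbate and 490 to 7 for both arms together.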

Results

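The data are RNA-seq gene counts from AE9a-driven mouse leukaemia cells of the spleen, in 8 libraries from 8 mice. The secondary transplants form 3 groups: sustained Tet2 knockdown with PBS (3 mice), PBS after doxycycline was withdrawn (2 mice, labelled Tet2-restored) and sustained knockdown with ascorbate (2 mice). A single primary-transplant knockdown library has no replicate. Total counts were 24.5, 24.0 and 27.1 M in mice 16, 17 and 19, 23.1 and 19.9 M in mice 21 and 23, 18.1 and 24.6 M in mice 28 and 30, and 34.2 M in mouse 12. Mitochondrial genes took 14.5% of counts in mouse 23 and 17.1% in mouse 28, against 9.09% to 11.4% in the PBS knockdown mice and 5.16% in the primary library. Within a group, log2 CPM correlated between libraries at 0.973 to 0.984 across genes, which are not independent replicates. The first principal component of the 8 libraries held 41.1% of the variance and the next 14.8%.

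Tet2, the hairpin's target and a dioxygenase that oxidises 5-methylcytosine, lies on chromosome 3 (133463679 to 133545139, GRCm38). Its level was 12.6, 12.8 and 13.4 CPM in the PBS knockdown mice 16, 17 and 19. In the mice labelled Tet2-restored it was 14.1 CPM (95% Poisson interval 12.6 to 15.7) in mouse 21 and 23.1 CPM (21.1 to 25.3) in mouse 23. Mouse 21 thus overlapped the knockdown mice, whose intervals reached 14.9 CPM, and its CPM level of Tet2 does not bear out its label. CPM does not correct for a trend with transcript length, which had a rho of −0.50 in mouse 21 against the PBS knockdown mean. The label of mouse 21 therefore cannot be judged from CPM alone. The ascorbate mice 28 and 30, kept on doxycycline, had 13.7 and 11.7 CPM, and the primary mouse 9.26 CPM. For the group labelled Tet2-restored the log2 fold change was 0.52 (SE 0.24, edgeR adjusted p 0.181). It was 0.84 without mouse 21 (adjusted p 0.0410), 0.12 without mouse 23 (0.820), and 0.99 with a length and GC offset (0.0758). Under ascorbate it was −0.034 (SE 0.24, adjusted p 0.945), a value that turned to 0.072 without mouse 30 and to 0.16 with the length and GC offset.

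Tet1 had 0 counts in each of the 7 secondary libraries, which allows up to 0.107 CPM in mouse 19 and 0.183 CPM in mouse 28, and 1 count in the primary library. Tet3, the other family member, stood at 98.8 ± 9.98 CPM (SD, n = 3) under knockdown with PBS, 72.7 ± 7.97 (n = 2) in the group labelled Tet2-restored and 66.7 ± 6.26 (n = 2) under ascorbate. Its log2 fold changes of −0.45 (SE 0.17) and −0.58 (SE 0.17) did not pass (adjusted p 0.118 and 0.0903). Runx1t1, a partner in the AE9a fusion (chromosome 4, 13743436 to 13893649), was at 105 ± 3.29 CPM under knockdown, 155 and 304 CPM in mice 21 and 23, 132 ± 3.37 under ascorbate and 184 CPM in the primary mouse on doxycycline. For the restored label its log2 fold change was 1.13 (SE 0.24, adjusted p 0.0507), 1.54 (0.00882) without mouse 21 and 0.55 (0.313) without mouse 23. Runx1 had log2 fold changes of 0.42 (SE 0.14, adjusted p 0.0940) and 0.37 (SE 0.14, adjusted p 0.153) in the same order. The files do not separate reads of the transgene from those of the endogenous Runx1 and Runx1t1.

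**Figure D1:**
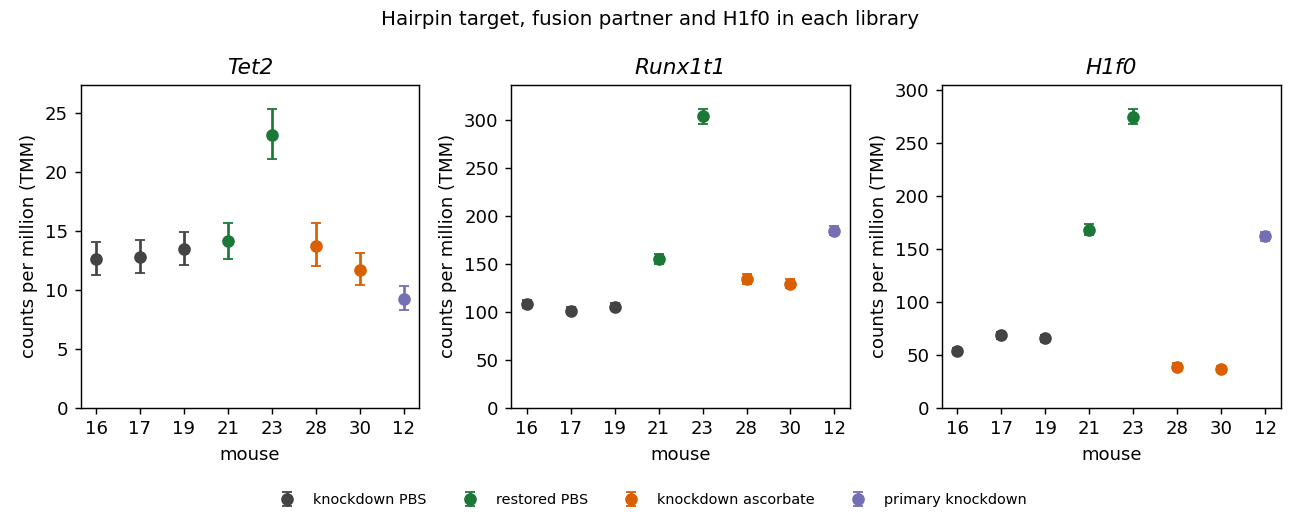
Level (CPM) of Tet2, Runx1t1 and H1f0 in each of the 8 mice, by group, with 95% Poisson intervals of counting error as bars. Tet2 stood at 23.1 CPM in mouse 23 and at 14.1 CPM in mouse 21, against 12.6 to 13.4 CPM in the PBS knockdown mice.

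Mice labelled Tet2-restored were compared with PBS knockdown mice to ask how leukaemia cells differ once doxycycline is withdrawn. Homologous recombination and Fanconi anaemia genes, which repair double-strand breaks and crosslinks, were lower as a list: 38 of 41 members had negative estimates and the median log2 fold change was −0.64 (camera adjusted p 8.68e-09, adjusted p = 0.721 with an estimated correlation) and −0.41 with a length and GC offset. Adjusted over the list alone, 20 members were lower and 1 higher, against 0 over all genes. The examples with the smallest p were Fancm at −1.56 (SE 0.29; 32.7 ± 5.57 to 11.1 ± 2.17 CPM), Atm at −1.55 (SE 0.31) and the nuclease scaffold Slx4 at −0.96 (SE 0.20), each with an adjusted p of 0.0502. Basophil, mast cell and eosinophil genes were higher as a list (median 1.16, camera adjusted p 2.80e-06, adjusted p = 0.263 with an estimated correlation), with 8 of 14 members higher adjusted over the list alone and 0 over all genes. Among them, Fcer1a, a chain of the high-affinity IgE receptor, was at 33.4, 66.2 and 50.4 CPM under knockdown and at 226 and 353 CPM off doxycycline, a log2 fold change of 2.53 (SE 0.32). Hdc, Il4 and Cma1 had values of 1.09 (SE 0.23), 0.95 (SE 0.20) and 1.33 (SE 0.28).

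Monocyte and macrophage genes had a median of −0.96 in this arm (camera adjusted p 0.000279, adjusted p = 0.721 with an estimated correlation), with 27 of 32 members below 0. Adjusted over the list alone, 2 were lower and 1 higher, and 0 passed over all genes. Vcam1, an adhesion molecule of splenic macrophages, was at 13.3 ± 2.60 CPM under knockdown and 1.67 ± 1.01 CPM off doxycycline, and Fn1, fibronectin, had a log2 fold change of 1.79 (SE 0.38). Macrophage scores were −0.39 in mouse 21, inside the range of the PBS knockdown mice (−0.48 to 0.51), and −1.51 in mouse 23. The recombination, mast cell and macrophage lists passed with camera at its preset correlation without each library in turn, with DESeq2 size factors, on library totals and with the length and GC offset, and did not pass with fry (adjusted p 0.191, 0.0515 and 0.287). G1/S and DNA replication genes (median −0.37, camera adjusted p 7.11e-05) and G2/M and mitosis genes (−0.38, 0.000279) were lower, with 4 and 0 members lower adjusted over the list alone. Their adjusted p was 0.721 and 0.760 with an estimated correlation, and 0.0975 and 0.151 without mouse 23. Ccne2, a cyclin of S phase entry, had a value of −1.34 (SE 0.29). Erythroid genes (median −0.52, or −0.80 with the length and GC offset, adjusted p 0.00360) were lower, with 3 members lower adjusted over the list alone, and reached 0.0703 without mouse 17 and 0.134 without mouse 23. HIF and hypoxia targets were higher (median 0.24, adjusted p 0.0383), with 5 higher and 2 lower adjusted over the list alone. Each of these 2 lists had an adjusted p = 0.721 with an estimated correlation, and the hypoxia list reached 0.144 without mouse 23, 0.0628 without mouse 17, 0.0557 without mouse 19, 0.0525 without mouse 28 and 0.0517 without mouse 30.

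Base excision repair and PARP genes, the group named by the study's title, did not pass as a list in this arm (median −0.10, camera adjusted p 0.364). Its score was 0.071 in mouse 21 and −0.26 in mouse 23, against −0.061 to 0.062 in the PBS knockdown mice. Parp1, the main target of PARP inhibitors, was its 1 member to pass adjusted over the list alone, at 390, 387 and 343 CPM in the PBS knockdown mice and 240 and 146 CPM in mice 21 and 23. The log2 fold change of Parp1 was −0.95 (SE 0.20, adjusted p 0.0520 over all genes). Other repair genes with values of this order were Polq, the polymerase of theta-mediated end joining, at −1.66 (SE 0.34), Rif1 at −1.36 (SE 0.30) and Prkdc at −1.30 (SE 0.32). Their list, non-homologous end joining, did not pass (median −0.29, camera adjusted p 0.0853), with 3 lower and 1 higher adjusted over the list alone. The smallest p over all genes belonged to H1f0, a linker histone of resting and differentiating cells, at 62.6 ± 7.94 CPM under knockdown and 221 ± 75.7 CPM off doxycycline, a log2 fold change of 1.82 (SE 0.21). The primary mouse, on doxycycline, had 162 CPM. Further genes at the same adjusted p of 0.0502 were the glycolytic enzyme Aldoc (2.09, SE 0.28), Shank3 (2.42, SE 0.37), Ccr9 (1.57, SE 0.24), Lgals7 (1.49, SE 0.23), Sapcd1 (1.36, SE 0.21), Topbp1 (−1.40, SE 0.21) and Eif2ak2 (−1.22, SE 0.18). Spi1, the myeloid factor PU.1, stood at 80.7 ± 14.5 and 158 ± 26.9 CPM (0.97, SE 0.19), and Tnf at 2.34 ± 0.701 and 9.56 ± 0.467 CPM.

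By edgeR, 0 of 12137 genes passed for the restored label, and the smallest adjusted p was 0.0502. Unadjusted, 3549 genes had a p under 0.05, against 607 by chance. DESeq2 called 1859 genes, limma voom 0 and limma-trend on FPKM 0, and edgeR called 1692 without mouse 21. Of the 31 lists, 13 passed (4 higher, 9 lower), 0 with an estimated correlation (adjusted p 0.263 to 0.764) and 0 with fry. Log2 fold changes fell with transcript length across genes (rho −0.39), and 10 lists passed after a length and GC offset. Each library's own length trend, against the PBS knockdown mean, had a rho of 0.45, −0.43 and −0.079 in mice 16, 17 and 19. It was −0.50 and −0.27 in mice 21 and 23, −0.30 and −0.12 in mice 28 and 30, and 0.38 in mouse 12. The trend thus differed among the PBS knockdown mice too.

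**Figure D2:**
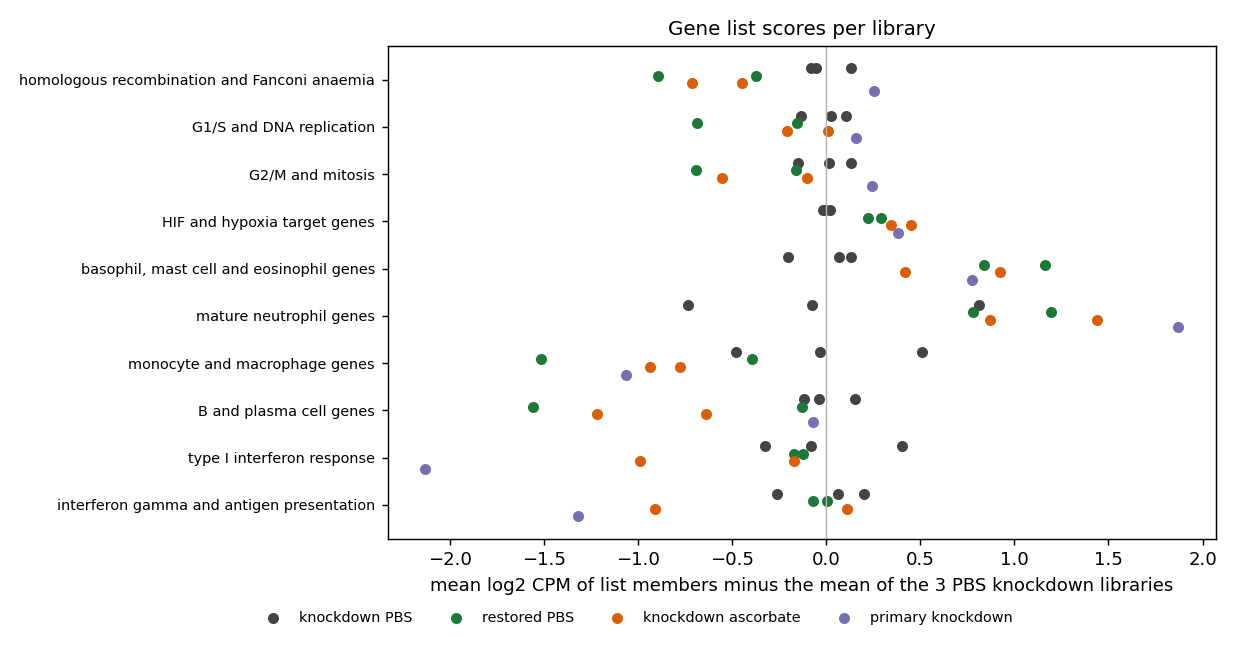
Score of 10 gene lists in each library: mean log2 CPM of the members minus the mean of the 3 PBS knockdown libraries. The recombination score was −0.37 and −0.90 in mice 21 and 23 and −0.71 and −0.45 in mice 28 and 30, against −0.08 to 0.13 in the PBS knockdown mice.

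Ascorbate, a cofactor that raises the activity of iron-dependent dioxygenases such as the TET enzymes, was compared with PBS under sustained knockdown. HIF and hypoxia targets rose as a list: 29 of 37 members had positive estimates and the median log2 fold change was 0.37 (camera adjusted p 2.95e-06, fry adjusted p 0.0378). Its adjusted p was 0.372 with an estimated correlation. The list's scores were 0.35 and 0.45 in mice 28 and 30, 0.22 and 0.29 in mice 21 and 23, and 0.38 in the primary mouse. A higher score was thus also seen in mice that did not receive ascorbate, the primary mouse among them. Each score is taken against the same PBS knockdown mice, whose own scores ran from −0.017 to 0.022. A low level in those mice could raise all the other scores, so these are not independent repeats. Under ascorbate 5 members rose and 0 fell over all genes, and 15 rose adjusted over the list alone. Among them were Ddit4, an inhibitor of mTORC1 signalling (1.42, SE 0.23; 22.5 ± 4.21 to 60.6 ± 18.7 CPM), Bnip3 (1.49, SE 0.26), Aldoa (0.80, SE 0.15) and the glucose transporter Slc2a1 (0.82, SE 0.16). Homologous recombination and Fanconi anaemia genes were lower in this arm too (median −0.49, 36 of 41 members below 0, camera adjusted p 4.95e-08, adjusted p = 0.721 with an estimated correlation). Here 4 members passed over all genes and 11 adjusted over the list alone, all lower. Slx4 (chromosome 16, 3979105 to 4003770) fell from 39.0 ± 4.51 to 11.1 ± 0.380 CPM (−1.82, SE 0.21, adjusted p 0.0124), and Gen1, a Holliday junction resolvase, fell as well (−1.33, SE 0.22). In the end joining list, which did not pass (median −0.14, adjusted p 0.339), the ligase Lig4 fell (−1.79, SE 0.38), 1 member of 4 that were lower adjusted over the list alone. Base excision repair and PARP genes did not pass in any member (median −0.045, adjusted p 0.355), and Parp1 was at 348 ± 5.41 CPM.

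Nuclear oxidative phosphorylation genes were higher as a list under ascorbate (45 of 50 members above 0, median 0.25, or 0.16 with the length and GC offset, camera adjusted p 0.000194, adjusted p = 0.739 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The oxidative phosphorylation score was 0.31 in mouse 28 and 0.15 in mouse 30, the latter inside the range of the PBS knockdown mice (−0.12 to 0.16). The mitochondrial share of counts was 17.1% in mouse 28 and 9.73% in mouse 30. Of the p53 targets, 2 rose and 1 fell over all genes, and 2 each adjusted over the list alone, and the list as a whole did not pass (median −0.12, mean 0.037, adjusted p 0.545). Bbc3, which encodes the cell-death protein PUMA (chromosome 7, 16308393 to 16318205), rose from 19.9 ± 4.46 to 74.5 ± 0.0887 CPM (1.90, SE 0.21, adjusted p 0.0103). Ccng2 rose by 1.72 (SE 0.19), and Rrm2b, a ribonucleotide reductase subunit, fell (−1.37, SE 0.29). Myc fell from 372 ± 44.7 to 168 ± 19.7 CPM, while the stem and progenitor list it belongs to did not pass (median −0.19, adjusted p 0.655). Gfi1b, a repressor of erythroid and megakaryocytic cells, fell from 433 ± 9.98 to 153 ± 10.5 CPM (−1.51, SE 0.24), and Spi1 rose by 0.84 (SE 0.19). Jun and Dusp1 fell (−1.36, SE 0.29, and −2.20, SE 0.45) in an immediate early list with a median of −0.23. That list's camera adjusted p was 0.0437, and the adjusted p was 0.721 with an estimated correlation, 0.453 without mouse 17, 0.0822 without mouse 30 and 0.0708 on library totals.

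Type I interferon response genes were lower as a list under ascorbate (36 of 39 below 0, median −0.54, camera adjusted p 8.80e-06, adjusted p = 0.721 with an estimated correlation). Parp12, Eif2ak2 and Trim30a fell (−1.19, SE 0.22; −0.90, SE 0.18; −1.04, SE 0.21), the 3 members past the threshold over all genes, against 5 adjusted over the list alone. Without mouse 30, whose score was −0.99 against −0.17 in mouse 28, the list's adjusted p was 0.170. Macrophage genes were lower (median −0.95, 28 of 32 below 0, camera adjusted p 0.000335, adjusted p = 0.721 with an estimated correlation), with 3 lower and 1 higher over all genes and 9 lower and 1 higher adjusted over the list alone. Vcam1 (−2.92, SE 0.43), the phagocytic receptor Mertk (−3.01, SE 0.59, from 1.22 ± 0.119 CPM) and the mannose receptor Mrc1 (−2.35, SE 0.53) fell. Fn1 of the same list rose by 2.03 (SE 0.38). Basophil, mast cell and eosinophil genes were higher (median 0.78, camera adjusted p 0.00141, adjusted p = 0.527 with an estimated correlation), with 2 of 14 higher over all genes, and 7 higher and 1 lower adjusted over the list alone. The chymase Cma1 rose by 1.38 (SE 0.28) and Il4 by 0.93 (SE 0.20). Neutrophil primary granule genes were higher (median 0.63, adjusted p 0.00989), with Prtn3, proteinase 3, up by 1.66 (SE 0.32), 1 member over all genes and 3 adjusted over the list alone. B and plasma cell genes had a median of −0.96 (adjusted p 0.00413) with 0 members past the threshold either way. These last 2 lists had an adjusted p = 0.721 with an estimated correlation, and the granule list reached 0.170 without mouse 30.

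Beyond the lists, the largest rises among genes named by rule were in Avil, advillin, an actin-binding protein (0.630 ± 0.157 to 14.9 ± 5.45 CPM; 4.55, SE 0.41, adjusted p 0.00883), Rapsn (3.48, SE 0.56), Il20rb (2.85, SE 0.49) and Eng (2.70, SE 0.56). Eng was at 34.3 CPM in mouse 28 and 6.65 CPM in mouse 30. Also higher were Sertad3, Ypel2, Mapt, Lgals7, Hoxb3 and Thsd4, by 1.76 to 1.90. The largest falls were in Jrk (7.10 ± 0.322 to 0.371 ± 0.00683 CPM; −4.24, SE 0.42) and in the zinc finger genes Zfp719 (−3.47, SE 0.47) and Zfp60 (−3.07, SE 0.53). Arhgap35, Nabp1, Fam212b, Yae1d1, Rpp38, Zfp953 and Zfp322a fell, with log2 fold changes from −2.57 to −2.07. Reads of zinc finger paralogs, of Trim30a and its relatives and of Hoxb3 and its antisense partner may be shared, so these values are uncertain.

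In total 347 of 12137 genes passed under ascorbate (132 higher, 215 lower) by edgeR, against 1286 with DESeq2 and 1105 with limma voom. On library totals 21.7% of calls were higher, against 38.0% with TMM factors. The count was 5 without mouse 16, 87 without mouse 17, 15 without mouse 19, 796 without mouse 21, 763 without mouse 23, 2 without mouse 28 and 7 without mouse 30. Of 53 named genes that passed, 3, 20, 9, 52, 52, 1 and 2 passed in the same order. Of these genes Avil alone passed in every alternative run. Without mouse 16 the adjusted p of Slx4 and Bbc3 was 0.0573, of Vcam1 0.0694, of Gen1 0.0978, of Parp12 0.101 and of Eng 0.166. Without mouse 28 the adjusted p of Slx4 was 0.0963, of Gen1 0.150, of Bbc3, Ccng2 and Jrk 0.0662, of Vcam1 0.102, of Parp12 0.102 and of Eng 0.271. Without mouse 30 these were 0.0731, 0.126, 0.0636 for each of Bbc3, Ccng2 and Jrk, 0.126 and 0.145, with Eng still past the threshold. Of the 31 lists 14 passed (7 higher, 7 lower), 0 with an estimated correlation (adjusted p 0.372 to 0.810) and 1 with fry. Across genes the log2 fold change fell with transcript length (rho −0.24), and 314 of the 347 genes were among 577 called with the length and GC offset.

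The arms were set against each other to test their difference directly. The PBS knockdown mice do not enter this difference, but they share in the estimate of spread and in the choice of genes tested. H1f0 (chromosome 15, 79028450 to 79030504) was the single gene past the threshold of 12137, at 168 and 275 CPM in mice 21 and 23 and 38.9 and 36.9 CPM in mice 28 and 30 (log2 fold change 2.56, SE 0.25, adjusted p 0.0222). Its adjusted p was 0.0524 without mouse 17, 0.101 without mouse 28 and 0.113 without mouse 30. The next genes did not pass, at adjusted p from 0.0565 to 0.0876. They were Wfikkn2 (−2.60, SE 0.32), Ccng2 (−1.56, SE 0.22), Gp1ba (1.25, SE 0.18), Tnf (2.73, SE 0.39), Avil (−3.06, SE 0.44), Slc20a1 (1.10, SE 0.17), Ranbp10 (−1.04, SE 0.16), Qsox2 (1.46, SE 0.23) and Gfi1b (1.65, SE 0.26). Tet2 differed by 0.56 (SE 0.27, adjusted p 0.336). The recombination list did not pass in this test (median −0.081, adjusted p 0.580; 25 of 41 members below 0), nor did the macrophage list (−0.058, 0.848) or the mast cell list (0.24, 0.0685). A test that misses its threshold does not show that the arms act alike. DESeq2 called 431 genes, limma voom 1 and limma-trend on FPKM 3, and 1966 genes had an unadjusted p under 0.05. Of the 31 lists 9 passed, 0 of them without each library in turn and 0 with an estimated correlation (adjusted p 0.576 to 0.923).

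**Figure D3:**
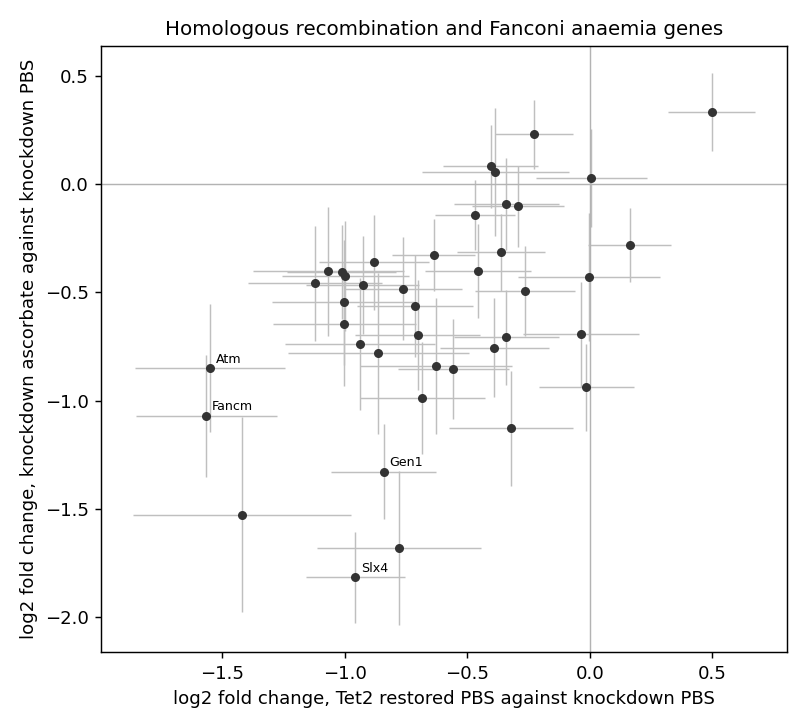
Log2 fold change of each tested member of the recombination and Fanconi anaemia list after doxycycline withdrawal (x axis) and under ascorbate (y axis), each against PBS knockdown mice, with SE as bars. Of 41 members, 38 lie below 0 on the x axis and 36 on the y axis, and Fancm, Slx4 and Gen1 are among those lower on both.

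Both arms pooled (4 mice) were then compared with the 3 PBS knockdown mice. Recombination and Fanconi anaemia genes fell as a list (median −0.63, 38 of 41 below 0, camera adjusted p 4.59e-10, adjusted p = 0.610 with an estimated correlation), with 3 members lower over all genes, and 24 lower and 1 higher adjusted over the list alone. The members past the threshold over all genes were Fancm (−1.29, SE 0.25), Slx4 (−1.32, SE 0.26) and Gen1 (−1.06, SE 0.21). Polq (−1.45, SE 0.28) and Rif1 (−1.18, SE 0.24) of the end joining list fell as well, while that list did not pass (median −0.20, adjusted p 0.105; 4 lower and 1 higher adjusted over the list alone). Macrophage genes were lower (median −0.90, 26 of 30 below 0, camera adjusted p 2.24e-05, adjusted p = 0.697 with an estimated correlation). Over all genes 3 macrophage genes were lower and 1 higher, and adjusted over the list alone 8 were lower and 1 higher. Vcam1 of this list fell (−2.94, SE 0.34). Hmox1, the haem oxygenase of iron-recycling cells, fell too (−1.66, SE 0.30), but belongs to the NRF2 oxidative stress list and not to the macrophage list. Mast cell and basophil genes were higher (median 0.95, camera adjusted p 4.82e-05, adjusted p = 0.610 with an estimated correlation), 3 of 13 over all genes, and 7 higher and 1 lower adjusted over the list alone. Cpa3, a mast cell carboxypeptidase, rose by 2.20 (SE 0.43; 16.8 ± 7.19 CPM in the controls), Cma1 by 1.36 (SE 0.24) and Il4 by 0.95 (SE 0.19).

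In the pooled comparison 10 more lists passed, with an adjusted p of 0.610 to 0.739 with an estimated correlation. Higher were mature neutrophil genes (median 1.11, adjusted p 0.00222; 0.0517 without mouse 30), granule genes (0.60, 0.00481), HIF targets (0.36, 0.000429) and oxidative phosphorylation genes (0.19, 0.000877), the last at 0.049 (0.472) with the length and GC offset. Lower were B and plasma cell genes (−0.80, 0.00275; 16 of 18 below 0), erythroid genes (−0.43, 0.00444; 0.141 without mouse 17) and G2/M genes (−0.36, 4.82e-05). In mice 23 and 28, with mitochondrial shares of 14.5% and 17.1%, B cell scores were −1.56 and −1.22 and G2/M scores −0.69 and −0.55. In mice 21 and 30 they were −0.13 and −0.64, and −0.16 and −0.10, so a difference in RNA quality stays open for these lists. Erythroid scores did not follow this under ascorbate (−0.27 in mouse 28, −0.42 in mouse 30). They were inside the range of the PBS knockdown mice (−0.44 to 0.23) in mice 21, 28 and 30, and below it in mouse 23 alone (−0.99). Also lower were G1/S genes (−0.22, 0.00779; 0.158 and 0.193 without mice 17 and 23), type I interferon genes (−0.33, 0.000752; 0.115 and 0.0641 without mice 19 and 30) and MYC genes (−0.12, 0.0274). The MYC list was at −0.22 with the offset, and its adjusted p was 0.204, 0.188 and 0.111 without mice 17, 23 and 28. Type I interferon scores were inside the range of the PBS knockdown mice (−0.32 to 0.40) in mice 21, 23 and 28, and below it in mouse 30 alone (−0.99).

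Further genes named by rule that rose in the pooled comparison were the troponin Tnni3 (3.38, SE 0.66), Rapsn (2.99, SE 0.61), Lat2 (2.62, SE 0.52), Shank3 (2.03, SE 0.41), Fn1, Cdk18, Aldoc, Lgals7, Gsn, Hoxb3 and Prtn3, the last 7 by 1.61 to 1.92. Those that fell were Hspa1b (−2.84, SE 0.56), Arhgap35 (−2.53, SE 0.35), Zfp719 (−2.40, SE 0.50), Camsap2 (−2.16, SE 0.45), Fam212b, Thap2, Ubxn2b, Kbtbd8, Zfp322a and Parp11, the last 6 with values from −1.90 to −1.58. Lat2 shares 952 exonic bases with Rfc2, and reads of Hspa1b and its near copy Hspa1a may be shared, so both values are uncertain. Spi1 rose by 0.91 (SE 0.17) and Bbc3 by 1.47 (SE 0.31). By edgeR 198 of 11694 genes passed (94 higher, 104 lower), with adjusted p no lower than 0.0435. The count was 0 without mouse 16, 17, 19 or 23, 813 without mouse 21, 4 without mouse 28, 1226 without mouse 30, 44 on library totals and 0 with the length and GC offset. DESeq2 called 1537 and limma voom 2520, and 3160 genes had an unadjusted p under 0.05. With that offset the adjusted p of Vcam1 was 0.0583, of Fancm 0.0615, of Slx4 0.0651, of Gen1 0.0763 and of Bbc3 0.0963. Of the 30 lists with enough members 13 passed, 0 with an estimated correlation and 0 with fry, and 8 of the 13 passed without each library in turn.

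The fold changes of the 2 arms share their 3 controls, which alone gives a positive correlation. Across 12137 genes the correlation was 0.58, against a mean of 0.38 (0.35 to 0.44) in 20 simulations of unchanged groups set against those controls. Covariance was 0.309 against 0.0744 simulated, a difference of 0.235. At an unadjusted p under 0.05, 653 genes were higher in both arms, against 53.4 simulated and 182 for independent lists, and 691 were lower in both, against 37.5 and 238. Since 3 controls cannot be split into parts of 2, part of the excess may come from the shared controls. The simulation drew genes independently and gave a mean of 570 unadjusted calls per arm, against 3549 for the restored label and 2862 under ascorbate. It held no trend with transcript length, which both arms had (rho −0.39 and −0.24). The excess over it therefore cannot tell a shared response from such a trend.

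The primary-transplant library was compared with the secondary PBS knockdown libraries. Transplant generation and PBS injections differ together between them, and the donor cells may differ too. The sample titles name no donor, so whether any of the mice share a donor leukaemia is not known from them. With 1 primary mouse, each p below rests on the spread of the other groups and no value was repeated in another primary mouse. Type I interferon genes were lower in the primary library: all 40 tested members were below 0, with a median log2 fold change of −2.14 (camera adjusted p 1.66e-67, adjusted p = 0.207 with an estimated correlation), 4 over all genes and 35 adjusted over the list alone. Irf7, the regulator of interferon induction, was at 42.1 CPM against 461 ± 123 CPM (−3.45, SE 0.47, adjusted p 0.0413), with Rtp4 at −3.30 (SE 0.37), Trim30a at −2.88 (SE 0.31) and Parp12 at −2.24 (SE 0.31). Interferon gamma and antigen presentation genes were lower in 31 of 31 members (median −1.22, camera adjusted p 2.84e-26, adjusted p = 0.207 with an estimated correlation), 0 over all genes and 17 adjusted over the list alone. Macrophage genes were also lower (−1.53, 9.95e-08; adjusted p = 0.467 with an estimated correlation), with 0 over all genes and 1 adjusted over the list alone. Mature neutrophil genes were higher (median 2.05, adjusted p 7.17e-07, adjusted p = 0.283 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone and 0 over all genes. HIF targets were higher (0.44, adjusted p 6.48e-07, adjusted p = 0.188 with an estimated correlation, fry adjusted p 0.0234), with 5 higher adjusted over the list alone and 0 over all genes. Mitochondrially encoded genes were lower (−0.92, adjusted p 6.48e-07, adjusted p = 0.330 with an estimated correlation), with 0 members past the threshold either way.

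Other cell type lists moved in the primary library as well. T and NK genes (median −1.001, adjusted p 0.00687; 11 of 13 below 0), endothelial and stromal genes (−0.95, 0.00809; 9 of 9), dendritic cell and MHC class II genes (−0.88, 0.00372; 16 of 19) and erythroid genes (−0.34, 0.00571; 23 of 27) were lower. Their adjusted p was 0.278, 0.207, 0.617 and 0.617 with an estimated correlation, and the erythroid list was at −0.23 with the length and GC offset and reached 0.0767 without mouse 16. Basophil, mast cell and eosinophil genes were higher (1.35, 0.000196; adjusted p = 0.207 with an estimated correlation), with 5 higher and 1 lower adjusted over the list alone. Recombination genes (0.27, 0.00571), G2/M genes (0.26, 0.00571), stem and progenitor genes (0.24, 0.00983), MYC genes (0.17, 0.00571) and stress response genes (0.26, 0.00628) were higher, and NF-kB genes (−0.48, 0.0193; 0.0623 without mouse 19) were lower. Their adjusted p was 0.669, 0.695, 0.207, 0.669, 0.617 and 0.330 with an estimated correlation. With the offset the recombination list was at 0.15 (0.122), the stem list at 0.15, the MYC list at 0.27 and the NF-kB list at −0.30.

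In the primary comparison 15 of 13024 genes passed by edgeR (9 higher, 6 lower), against 231 with DESeq2 and 279 with limma voom, and 1184 had an unadjusted p under 0.05. Named by rule as higher were Suclg2 (6.22, SE 0.82; 14.7 CPM), Stard13 (4.93, SE 0.57), Sumf1 (4.59, SE 0.62), the myelin protein Pmp22 (4.34, SE 0.36; 28.7 against 1.41 ± 0.362 CPM) and St6gal1 (3.23, SE 0.48). Trim30d (−5.96, SE 0.59) and the fucosidase Fuca2 (−2.19, SE 0.29) were lower, and reads of Trim30a and Trim30d may be shared. The count was 45 without mouse 16, 6 without mouse 17, 9 without mouse 19, 10 without mouse 21, 9 without mouse 23, 27 without mouse 28 and 28 without mouse 30. Without mouse 17 the adjusted p of Irf7 was 0.112, of Suclg2 0.107, of Sumf1 0.0994, of St6gal1 0.112, of Parp12 0.0585 and of Fuca2 0.0668. That of Irf7 was 0.0948 without mouse 21 and 0.0968 without mouse 23, and these 6 genes passed without mouse 28 or 30. Stard13, Pmp22, Trim30d, Rtp4 and Trim30a passed in every alternative run in which they were tested. Of the 31 lists 17 passed (8 higher, 9 lower), 0 with an estimated correlation and 2 with fry.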

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

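All values in this part come from the planned test of mice labelled Tet2-restored against ascorbate-treated mice, and the offset for length and GC was chosen after the result was seen. Each is given because the 2 arms differed in that test. H1f0, the linker histone, differed by 2.56 on the log2 scale (SE 0.25, adjusted p 0.0222), with mice 21 and 23 above and both ascorbate mice below the PBS knockdown mice. The primary mouse, on doxycycline, had 162 CPM. Its adjusted p was 0.0524 without mouse 17, 0.101 without mouse 28 and 0.113 without mouse 30.

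Among the lists, none passed with an estimated correlation, at the second p given for each. G1/S and DNA replication genes differed by a median of −0.28 (adjusted p 0.000241; 0.796), with 34 of 39 members lower in mice 21 and 23, and reached 0.343 without mouse 23. Iron and 2-oxoglutarate dioxygenase genes, the class that TET enzymes belong to, differed by −0.29 (0.00188; 0.576), 29 of 38 lower, and reached 0.0724 without mouse 21. Unfolded protein and integrated stress response genes differed by −0.29 (0.00210; 0.738), 23 of 29 lower, and reached 0.0791 without mouse 23 and 0.203 without mouse 30. HIF and hypoxia targets differed by −0.25 (0.0197; 0.576), 27 of 37 lower, and reached 0.152 without mouse 21 and 0.0778 without mouse 30. The p53 targets differed by −0.19 (0.0197; 0.576), 17 of 25 lower, and reached 0.0604, 0.0791 and 0.0916 without mice 21, 23 and 28.

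Type I interferon genes differed by 0.37 (adjusted p 0.00581; 0.923), with 28 of 39 members higher in mice 21 and 23, and reached 0.0604 without mouse 21 and 0.824, with the sign turned, without mouse 30. Interferon gamma and antigen presentation genes differed by 0.22 (0.0319; 0.923), 21 of 29 higher. That list reached 0.0518, 0.103, 0.0791 and 0.258 without mice 16, 21, 23 and 30, with the sign turned in the last, and 0.0736 with the length and GC offset. The interferon scores of the ascorbate mice were −0.17 in mouse 28 and −0.99 in mouse 30 for the type I list. Immediate early and heat shock genes differed by 0.57 (0.0397; 0.738), 18 of 28 higher. They reached 0.385 without mouse 21, 0.104 without mouse 28, 0.0666 on library totals and 0.0573 with the offset. Sex-linked genes were listed as a check of donor and host cells, but their level here does not tell these apart. The 5 tested members differed by a median of −0.42 (0.0268 and 0.738). They reached 0.0604, 0.0791 and 0.166 without mice 21, 23 and 30, and 0.0537 with the offset.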

How the results depend on the processing

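The length and GC offset and the threshold of 0.1 were chosen after seeing the data. No paired analysis was possible because no mouse number is shared between groups. Leaving out a mouse of an arm leaves 1 in it, which is assumed to vary like the other groups.

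For the restored label the count of genes was 0 with edgeR on TMM factors, library totals, all 8 libraries, the 2 groups alone and the offset, and with limma voom and limma-trend on FPKM. It was 367 with DESeq2 size factors, 345 with upper quartile factors, 1859 with the DESeq2 test, 2207 with no filter on low counts, 321 at 1 CPM in 2 libraries, 506 at a mean of 5 CPM and 2039 at a threshold of 0.1. Leaving out 1 library gave 0 to 1692 (without mouse 21). The smallest adjusted p by edgeR on TMM factors was 0.0502, close to the threshold. The cause of the differences between these counts was not tested.

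Under ascorbate the count was 347. It was 1286 with DESeq2, 1105 with limma voom, 1498 with no filter, 855 in a fit of the 2 groups alone, 577 with the offset, 1098 at a threshold of 0.1, and 2 (without mouse 28) to 796 (without mouse 21) with 1 library left out; the cause was not tested. For the arms compared the count of 1 became 431 with DESeq2, 582 with no filter, 3 with either FPKM pseudocount, 3 in a fit of all 8 libraries, 3 with the offset, 59 at 0.1, and 0 to 5 with 1 library left out. For both arms together the count of 198 became 44 on library totals, 1537 with DESeq2, 2520 with limma voom, 1086 with no filter, 369 at a mean of 5 CPM, 0 with the offset, 122 at 2-fold or more, 1446 at 0.1, and 0 to 1226 with 1 library left out. For the primary library the count of 15 became 231 with DESeq2, 279 with limma voom, 467 with no filter, 5 at 1 CPM in 2 libraries, 3 at a mean of 5 CPM, 8 with an FPKM pseudocount of 0.1, 31 at a threshold of 0.1, and 6 to 45 with 1 library left out. A higher threshold or a 2-fold minimum changes a count by construction, and for the rest the cause was not tested.

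Gene lists that passed numbered 0 with an estimated correlation in each of the 5 comparisons. With fry they numbered 0 for the restored label, 1 for ascorbate, 0 for the arms compared, 0 for both arms together and 2 for the primary library. Leaving out 1 library gave 8 to 12 lists for the restored label (13 with all), 10 to 15 for ascorbate (14), 7 to 10 for the arms compared (9), 10 to 14 for both arms together (13) and 17 to 19 for the primary library (17). The cause was not tested. At the preset correlation the recombination, macrophage and mast cell lists passed in each arm without each library in turn.

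Tet2 had a log2 fold change of 0.12 to 0.84 for the restored label with 1 library left out. Under ascorbate its value near 0 ran from −0.15 to 0.072 (without mouse 30) and was 0.16 with the offset. Tet2 has no value from FPKM, since it is below the filter there. Among other values near 0, the sign turned for Xist for the restored label (0.16 with the offset), Runx1 between the arms (−0.026 to 0.10 with 1 library left out) and Runx1 in the primary library (−0.017 with the offset). Tet3 in the primary library had −0.039 with upper quartile factors, −0.0019 at a mean of 5 CPM, −0.16 with the offset and −0.056 to 0.13 with 1 library left out. Between the arms, the adjusted p with 1 library left out ran from 4.39e-10 to 0.824 for type I interferon genes and from 3.27e-09 to 0.258 for interferon gamma genes, each with its sign turned without mouse 30. The cause was not tested.

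Of 1032 further values for genes named under ascorbate, 763 kept direction and side of the threshold and 269 kept direction alone. These numbers were 16 and 3 of 19 for the arms compared, 432 and 302 of 734 for both arms together, and 148 and 33 of 181 for the primary library. On library totals the median of all genes moved to −0.12 under ascorbate and to 0.13 between the arms, and upper quartile factors moved the latter to 0.11. Of 52459 genes in the file, 16477 to 18659 had a count in a library and 12137 were tested among the secondary libraries; how much of this is due to depth was not tested. A count of 0 allows up to 0.183 CPM in mouse 28.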

Other observations

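The tests of the recombination list, the tests of other host cell types and the length test of the mast cell list were chosen after the result was seen. The other lists that passed off doxycycline and under ascorbate come first. Off doxycycline, neutrophil primary granule genes (median 0.53, adjusted p 0.0227) and mature neutrophil genes (0.80, 0.0383) were higher. B and plasma cell genes (−0.72, 0.0281), MYC and ribosome biogenesis genes (−0.18, 0.0208), unfolded protein and stress response genes (−0.29, 0.0246) and sex-linked genes (−0.56, or −0.28 with the length and GC offset, 0.0135) were lower. Their adjusted p was 0.721, or 0.764 for the MYC list, with an estimated correlation. Without mouse 23 they reached 0.129 for mature neutrophil, 0.549 for B cell, 0.547 for MYC and 0.130 for stress genes, and without mouse 21 they reached 0.150 for granule, 0.0820 for mature neutrophil and 0.0511 for sex-linked genes. With the length and GC offset they reached 0.0536 for granule, 0.103 for mature neutrophil and 0.165 for sex-linked genes. Without mouse 17 they reached 0.0555 for granule and stress, 0.0628 for B cell and 0.115 for MYC genes, and without mouse 16 they reached 0.0523 for granule and 0.0808 for mature neutrophil genes.

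Under ascorbate the next 5 lists each had an adjusted p of 0.721, or 0.810 for G2/M, with an estimated correlation. Mature neutrophil genes (1.17, 0.00380; 0.0771 without mouse 30) were higher. G2/M genes (−0.32, or −0.19 with the offset, 0.00140; 0.395 without mouse 28) and TET and DNA methylation genes (−0.29, 0.0453; 0.0631, 0.0687 and 0.0887 without mice 16, 17 and 30) were lower. NF-kB genes (0.25, 0.0372; 0.0577, 0.0633 and 0.148 without mice 16, 17 and 28) and NRF2 genes (0.20, or 0.13 with the offset, 0.0453; 0.0605 to 0.0997 without mouse 16, 19, 21, 23, 28 or 30, 0.102 on library totals, 0.117 with the offset) were higher, with Icam1 (0.92, SE 0.16) and Sqstm1 (0.72, SE 0.13) past the threshold.

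Repair of double-strand breaks and crosslinks may be expressed at a lower level in both arms, as a hypothesis. A trend with transcript length and GC content was argued against as the whole cause. The list's median of −0.63 was at percentile 0 of 10000 random lists matched on expression, length and GC, and stayed at −0.44 after the offset. That percentile is taken over genes and does not measure spread between mice. With a lower share of cycling cells, cell cycle members would fall at least as much as the list. Under ascorbate 78 such members fell less, by 0.255 (bootstrap 95% interval over members 0.144 to 0.512), so that prediction was missed. For the restored label the difference was 0.262 (−0.00712 to 0.474), which leaves it open. These intervals do not measure spread between mice, and the list was picked for its fall, so neither result excludes a lower share of cycling cells. The G2/M scores were −0.55 and −0.10 in mice 28 and 30. Of 35 splits of the 7 secondary libraries into 4 and 3, 1 gave a median as low, the real one, and the others ran from −0.43 to 0.61, but the list was picked from 31 after its fall was seen, so chance is not excluded. The scores of −0.90 and −0.71 in mice 23 and 28 go with mitochondrial shares of 14.5% and 17.1%, and those of −0.37 and −0.45 in mice 21 and 30 with 9.49% and 9.73%, so a difference in RNA quality stays open. The loss of doxycycline, the return of Tet2 and an effect of ascorbate through other enzymes stay open and were not tested.

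Zinc finger genes, most of them DNA-binding repressors, may be lower under ascorbate as a family, a pattern noticed in the data. Of 264 tested Zfp genes 18 were lower (6.82%), against 1.66% of 11873 others, shares that restate what was noticed, and 180 of 264 had estimates below 0. Their median of −0.34 was at percentile 0.01 of random lists matched on expression, length and GC, and at percentile 0 of lists matched on expression alone. Taken over genes, this argues against the length trend as the whole cause and against a few genes alone. The family was picked from these same data, and percentiles over genes do not measure spread between mice. Zfp scores were 0.19, −0.17 and −0.024 in the PBS knockdown mice 16, 17 and 19. They were −0.16 and −0.12 in mice 21 and 23, and −0.35 and −0.41 in the ascorbate mice 28 and 30. The offset left a median of −0.15, and left-out libraries gave −0.22 (without mouse 16) to −0.42 (without mouse 17). Reads shared between these paralogs stay open, and no biological explanation was tested.

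Macrophage genes lower with mast cell genes higher may reflect a different mix of cells, as a hypothesis. The primary library, kept on doxycycline without ascorbate, had the pair too, with a macrophage median of −1.53 and a mast cell median of 1.35. Its comparison and those of both arms use the same PBS knockdown mice. Unusual levels in those mice could give the pair in each comparison, so the primary library is not an independent repeat. Fewer host cells of every type stays open. In both arms together 40 mast cell, basophil, neutrophil, T and NK members had a median of 0.916 (95% interval 0.544 to 1.24). The intervals in this paragraph are bootstraps over members and do not measure spread between mice. These members leave out lists that fell, and the leukaemia cells may express myeloid genes themselves. Over 115 members of all 9 cell type lists besides macrophages the median was −0.0176 (−0.325 to 0.274), with B and plasma cell genes at −0.80 and erythroid genes at −0.43. Fewer host macrophages could not be decided: rho across members between the control mice 19 and 16 and the fall in both arms was −0.172 (−0.532 to 0.247). The bound set for that test was wrong, a judgement made after the result was seen, because a change in share moves all members by 1 fold and gives no rho (28 of 30 members were higher in mouse 19 than in mouse 16). For the mast cell list the length trend was argued against as the whole cause, at percentile 100 of matched lists and a median of 1.04 after the offset. The list was picked after its rise was seen, and a percentile over genes does not measure spread between mice. Differentiation of the leukaemia cells and host mast cells both stay open, and the sort for AE9a-positive cells would remove host cells.

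For both arms together, 2 of the 35 splits, the real one included, called at least as many genes as the real one (198). The other of these called 319 and set mouse 21 with the 3 PBS knockdown mice against mice 23, 28 and 30. At least as many lists were called in 8 splits, the real one included (13 in the real one, 15 in the highest other). Chance cannot be excluded for either count.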
